A study of Rattus norvegicus with 5 samples.

How the data were processed

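The series holds 5 single-cell RNA sequencing samples of rat retina: 2 control samples (0 weeks) and 1 sample each from rats 2, 4 and 8 weeks into diabetes. Count matrices of 4 samples were used, which are control replicate 2 and the 3 diabetic samples. Control replicate 1 was not analysed here. Per the labels, diabetes was induced with streptozotocin at 45 mg/kg, rats with a blood glucose above 200 mg/dL were taken as diabetic and fed a diet rich in fat and sugar, and controls received citrate buffer. Retinas were digested in 0.25% trypsin at 37 °C for 40 min and passed through a 40 µm strainer, and red cells were lysed.

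The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, for 25399 genes with Ensembl identifiers, and no normalization was applied by the authors to these counts. The submitters' processing notes and the file headers name Cell Ranger 3.0.1, and the notes name the Rnor_6.0 build. The annotation release is not stated, 128 symbols belong to more than 1 gene, and gene identities are those of the files. Every deposited barcode had at least 500 UMIs, so droplets of lower content could not be examined. The libraries held 9742 barcodes and 25068331 UMIs (control), 16128 and 34177860 (2 weeks), 10717 and 20151789 (4 weeks), and 7649 and 24604362 (8 weeks).

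Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Doublet scores were computed per library with Scrublet as implemented in scanpy 1.11.5 (simulation ratio 2). The top-scoring 0.8% of cells per 1000 barcodes were removed, since its automatic threshold called almost none in 2 libraries. Kept cells were log-normalised, 2000 variable genes were chosen within libraries, and 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2) gave 28 clusters of the 4 libraries together. Clusters took a class name from marker lists of 25 cell types fixed before the data were examined, and a cluster without a clear best class stayed unnamed. Marker genes that named a class were kept in the lists, and some are given below for that class. Examples are Arr3, Pde6c and the opsins in cones, Glul and Aqp4 in Müller glia, and P2ry12 in microglia. Assigning each kept cell to the nearest cluster mean returned its class in 99.7% of cells, although the same cells made those means. Barcodes outside the filters were not clustered and took the class of the nearest mean.

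With 1 library analysed per group, cells are not replicates and no test between groups was possible. UMIs were therefore summed per library and class, expressed as CPM, the usual counts scaled to the UMI total of the class, and given as log2 ratios to control with 0.5 counts added to each sum. Shares carry exact (Clopper-Pearson) binomial 95% intervals and ratios carry exact conditional binomial 95% intervals. These cover counting error only and leave out differences between animals, dissections and library preparations. A sum of 0 was set to 3 counts and its ratio given as a bound. A class was compared where each library held at least 50 cells of it, which left 6 classes. A gene was used in a class at a mean of at least 20 CPM over the 4 libraries and at least 30 summed UMIs over the pair of libraries. The 3 comparisons of diabetic samples with control share 1 control library. Genes at least 2-fold higher, or lower, at all 3 times were therefore counted with each library in turn as the reference. They were also counted in 20 simulations that drew Poisson counts for all 4 libraries from 1 expression profile.

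For 34 gene lists fixed before the data were examined, the median log2 ratio of the used members (at least 5) was set against 10000 random lists of the same size matched on mean expression in 20 bins. A median outside the central 95% of random lists is called apart. Genes were named by a rule fixed at the same time. Per class it takes the 8 genes higher and the 8 lower at all 3 times with the largest smallest ratio, and per time the 4 highest and 4 lowest others. Each must have an interval that excludes 0 and a class CPM at least that of all cells of the library (0.5 of it for rods). It adds up to 4 members of each list described and a few fixed genes. Ribosomal, mitochondrial and unnamed genes were not named. Any other gene given was chosen after its values were seen, and so were the lists described and plotted, which were those with the widest departures or known roles in diabetic retina. RNA shared between droplets was estimated per class and library from rod genes in classes that should lack them.

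Alternatives planned before the data were examined were other filters on UMIs and mitochondrial share, doublets kept, every deposited barcode, Leiden resolutions 0.5 and 2.0, each library clustered alone, TMM scaling (edgeR 4.0.16 in R 4.3.3), cells thinned to 1000 UMIs, subtraction of free RNA, mean CPM of 5 and 100, thresholds of 1.5-fold and 3-fold, and totals without ribosomal and mitochondrial genes. Alternatives added after the data were seen were at most 40% mitochondrial UMIs, cells with markers of another type left out, the cell with the most UMIs of each class and library left out, and each diabetic library left out. Values within single clusters of at least 30 cells were also added then. Cells left out for markers of another type had at least 2 UMIs of those markers in Müller glia, amacrine cells and microglia. In bipolar cells this alternative instead left out the cluster led by Car8, Pcp2 and Qpct, which carried bipolar markers. The intervals, the list procedure and the fold threshold were tested on simulated data: intervals covered the true ratio for 95.4 to 96.7% of genes, and each of 20 raised lists was called apart in every class and library. Of 20 unchanged lists, 0 to 4 were called. The simulated counts were Poisson, which the intervals assume, and list members varied independently. UMIs clumped in few cells, or members that vary together, were therefore not covered, and real coverage may be lower. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.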

Results

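Droplet single-cell RNA sequencing was carried out on retinas of control rats and of rats 2, 4 and 8 weeks after streptozotocin, a toxin of pancreatic beta cells. The series addresses how retinal cells differ in early diabetes. The analysis used 1 control library (0 weeks) and 1 library per diabetic time. After filtering, 6969 control cells, 11125 cells at 2 weeks, 7744 at 4 weeks and 4357 at 8 weeks remained, which is 71.5, 69.0, 72.3 and 57.0% of the barcodes. They held 13909250, 21273284, 11762238 and 11424902 UMIs, with medians of 1022, 1133, 902 and 1422 UMIs per cell. No group had more than 1 analysed library, so all intervals cover counting error only. Time since streptozotocin could not be told apart from age, diet, animal or preparation. Transcripts of the Y-linked gene Eif2s3y stood at 78.7, 61.4, 62.4 and 80.6 CPM in the 4 libraries and those of Kdm5d at 29.8, 20.5, 24.5 and 33.2 CPM.

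The first comparison asked how the cellular make-up of the retina differed from control. Rods were the main class at every time, with 80.2% of control cells, 71.7% at 2 weeks, 86.1% at 4 weeks and 72.3% at 8 weeks. Müller glia, the radial support cells of the retina, made up a smaller share at each diabetic time: 5.71% in control against 3.67, 3.93 and 3.83% (log2 ratios -0.64, -0.54 and -0.57, with intervals of -0.84 to -0.44, -0.76 to -0.32 and -0.84 to -0.31). Bipolar cells made up 3.36% of control cells and 8.78, 3.51 and 7.62% of diabetic cells, and amacrine cells 3.04, 3.55, 3.65 and 7.21%. Microglia, the resident immune cells, made up 3.16% of control cells, 2.21% at 2 weeks and 0.98% at 4 weeks (log2 ratio -1.68, -2.08 to -1.30) and stood at 3.86% at 8 weeks. Cones stood at 1.35, 1.62, 0.68 and 2.64%. Endothelial cells varied from 1.62% in control to 4.18, 0.50 and 1.33%, and erythroid cells numbered 45, 46, 19 and 26.

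The mitochondrial filter weighed unequally on the classes. Barcodes above the limit were not clustered and took the class of the nearest cluster mean, which was not checked for them. By that class, the filter removed 84.7% of bipolar barcodes in control and 64.7, 80.8 and 86.1% in the diabetic libraries. Of rod barcodes it removed 6.1, 9.0, 7.4 and 10.2%. The higher bipolar share at 2 weeks (log2 ratio 1.38, 1.18 to 1.60) became 0.14 when cells with up to 40% mitochondrial UMIs were kept and -0.13 at a limit of 10%, so its direction depended on the filter. At 8 weeks the bipolar ratio of 1.18 (0.94 to 1.43) stayed above 0 under every filter tried. The Müller ratios kept their sign but were smaller under some filters, at -0.29 at 2 weeks with at most 10% mitochondrial UMIs and at -0.23 at 4 weeks over every barcode. For Müller glia, 4.2% of control barcodes and 17.5, 21.0 and 14.1% of diabetic barcodes exceeded the mitochondrial limit of 20%. The plot of shares by class shows both quantities.

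**Figure D1:**
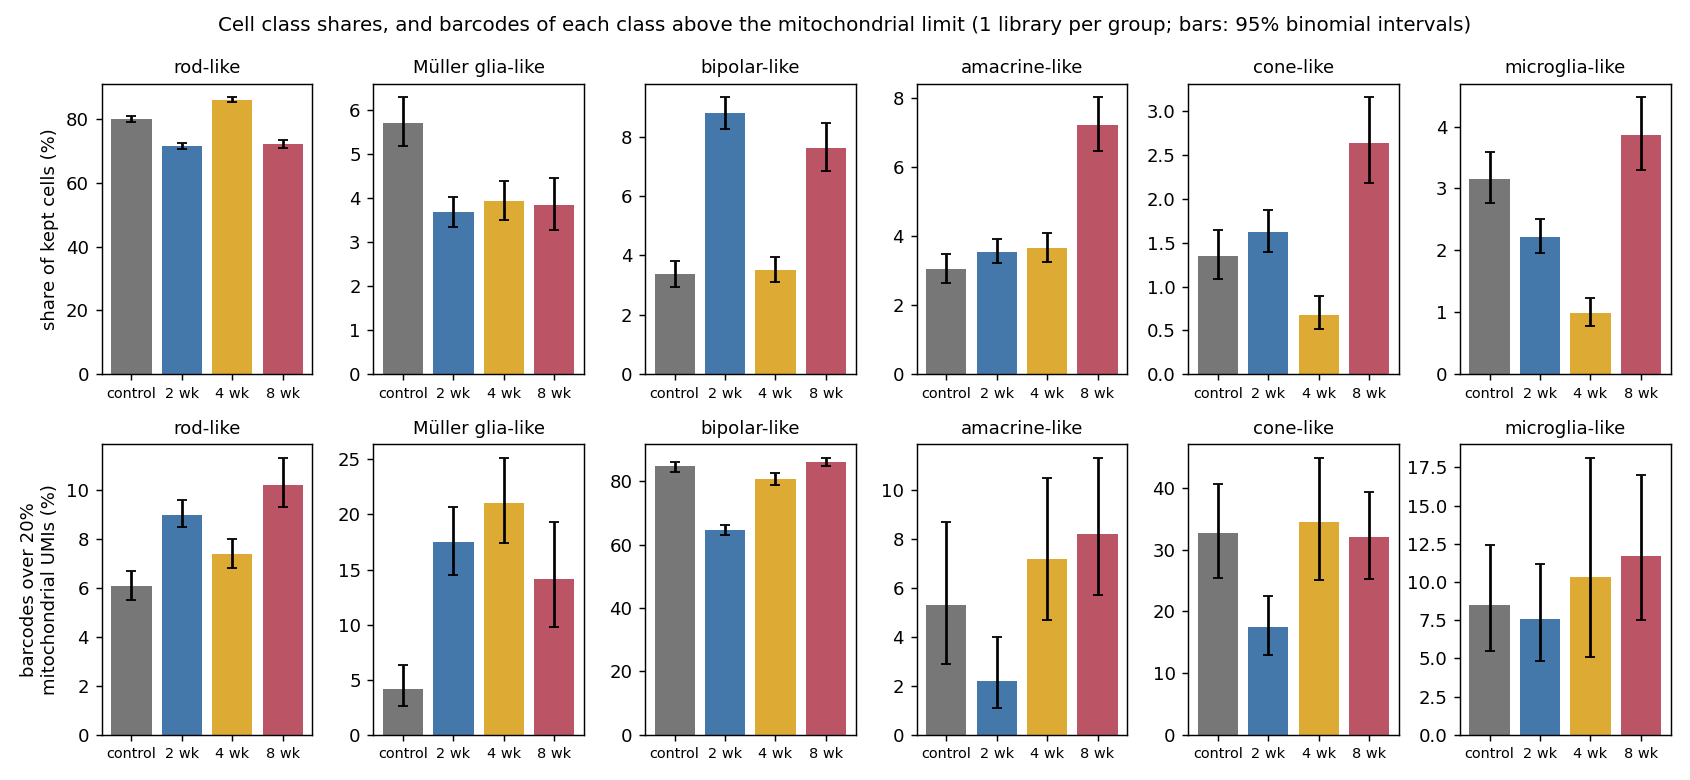
Share of kept cells per class (percent of cells in the library) and percent of barcodes of each class with over 20% mitochondrial UMIs, for the control and the 2-, 4- and 8-week diabetic libraries; bars are exact binomial 95% intervals that cover counting error only. Müller glia lie at 5.71% in control and at 3.67 to 3.93% in the diabetic libraries. Of barcodes classed as bipolar, by cluster or by nearest cluster mean, 64.7 to 86.1% exceed the mitochondrial limit.

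The second comparison asked which genes differed from control within each class. At all 3 times, between 7 and 46 genes per class were at least 2-fold higher or lower. With control as the reference there were 2 higher and 6 lower in rods (of 5934 genes), 10 and 4 in Müller glia, 34 and 12 in bipolar cells, 13 and 0 in amacrine cells, 4 and 3 in cones, and 5 and 11 in microglia. Without the 8-week library the total was 179 in rods in place of 8, and in bipolar cells it was 10 in place of 46 with up to 40% mitochondrial UMIs and 17 with doublets kept. Simulated libraries with Poisson counting error alone gave means of 0.0, 0.2, 2.5, 0.35, 0.85 and 0.15 such genes in these classes. Other libraries taken as the reference gave more genes in some classes and fewer in others. With the 2-week library there were 114 in rods, 62 in Müller glia, 16 in bipolar cells, 51 in amacrine cells, 21 in cones and 150 in microglia, and with the 4-week library 29, 23, 39, 43, 43 and 171. With the 8-week library there were 6, 26, 215, 6, 8 and 11. A control library that stood apart for any reason would also yield such genes. Of 397 combinations of a list, a class and a time, 74 medians lay above and 64 below the central 95% of random lists.

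In rods, the photoreceptors of dim light, Chac1, Asns, Sesn2 and other genes named for the lowest ratios were far lower at 2 weeks and 4 weeks, with smaller differences at 8 weeks. Chac1, which degrades glutathione and is a target of the transcription factor ATF4, stood at 181 CPM in control and 0.2 CPM at 2 weeks (2 UMIs, log2 ratio -9.32, -12.69 to -7.78) and stood at 13.8 and 51.0 CPM at 4 and 8 weeks. Asns, which makes asparagine, stood at 266, 9.8, 18.1 and 211 CPM, with a log2 ratio of -4.75 (-5.08 to -4.44) at 2 weeks. Sesn2, a sensor of leucine, followed the same order at 217, 9.2, 33.7 and 146 CPM, as did Mthfd2, a mitochondrial folate enzyme, at 312, 14.5, 104 and 238 CPM. The amino acid transporter Slc7a1 stood at 64.8, 2.3, 1.0 and 34.3 CPM and its relative in function Slc1a4 at 67.9, 2.8, 18.1 and 48.9 CPM. The stress-induced transcription factor Atf3 stood at 418, 25.2, 96.3 and 229 CPM. Lower at all 3 times were also Siah2, a ubiquitin ligase (-2.21, -1.40 and -0.81), Dusp8, a phosphatase of MAP kinases (-1.55, -1.41 and -0.78), the clock repressor Bhlhe41 (-1.59, -1.18 and -0.78), the transcriptional repressor Mnt (-1.08, -0.85 and -0.80) and the centriolar gene Cep295 (-2.56, -1.76 and -1.35).

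The list of the unfolded protein response had rod medians of -0.51, -0.24 and -0.30 at 2, 4 and 8 weeks, each apart from random lists, with 10, 11 and 11 of 15 members lower, and under TMM scaling the 2-week median was -0.13. The call was lost at 2 weeks at a mean CPM of 5 (-0.39), and at 4 weeks at a mean CPM of 5 (-0.17) and with at most 10% mitochondrial UMIs (-0.19). Its members parted widely at 2 weeks: Trib3, a pseudokinase, stood at 406 CPM in control and 18.9 CPM at 2 weeks, and Herpud1, which serves degradation at the endoplasmic reticulum, at 663 and 59.7 CPM. Atf4 itself had a log2 ratio of -0.51 (-0.54 to -0.48) and Ddit3 of -1.60 (-1.69 to -1.52), while 5 members were higher. The median of all genes used in rods stood at -0.27 at 2 weeks, and TMM scaling moved rod ratios of that time by 0.38, so that small rod ratios at 2 weeks depend on the scaling. The same scaling moved ratios by -0.17 in microglia at 2 weeks and by -0.11 in bipolar cells at 8 weeks.

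Nuclear-encoded genes of energy metabolism were higher in rods at 2 and 4 weeks. The nuclear-encoded oxidative phosphorylation list had medians of 0.79 and 0.44, with 29 and 27 of 31 members higher, and the glycolysis list medians of 0.59 and 0.57, with 11 and 13 of 16 higher. Ndufa4, a subunit of cytochrome oxidase, stood at 1265 CPM in control and at 5439 and 2525 CPM (log2 ratios 2.10 and 1.00), and Cox6c at 433, 1138 and 855 CPM. The glycolytic enzymes Aldoa (1.27 and 0.86) and Pgam1 (1.19 and 1.05) were among the higher members. The oxidative stress defence list had medians of 0.66 and 0.50, with Prdx2, a peroxiredoxin, at 218, 617 and 506 CPM in control and at these times. Mitochondrially encoded genes had a median of 0.92 at 2 weeks (13 of 13 members higher), -0.15 at 4 weeks (10 of 13 lower, within random lists) and 0.33 at 8 weeks.

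Ip6k2, an inositol hexakisphosphate kinase, stood at 299.9 CPM in control and at 597, 598 and 604 CPM in the diabetic libraries (log2 ratios 0.99, 1.00 and 1.01). Ypel4 (1.99, 3.30 and 1.24), Abhd12, a lysophospholipase (1.21, 1.42 and 0.79), and Asmt, the last enzyme of melatonin synthesis (1.27, 1.13 and 0.80), were also higher at all 3 times, as were Gpr160, Pter, Mlf1 and Sh2d3c, by 0.75 to 1.19. Cdkn1a, which encodes the cell cycle inhibitor p21, was higher by 2.48, 2.84 and 1.87, and the list of apoptosis and p53 targets had a median of 0.39 at 4 weeks (9 of 11 higher). Egr1 was higher at 2 weeks alone, at 516 CPM against 23.2 CPM in control and 13.6 and 12.5 CPM later. Ripply3, a transcriptional corepressor, had 4 and 2 UMIs in the control and 2-week libraries and stood at 48.2 and 52.2 CPM at 4 and 8 weeks (6.13, 4.92 to 8.18, and 6.24, 5.04 to 8.29). Khdrbs3 was higher at 4 weeks (3.11), and Ccnd2, a cyclin, and Akap6 at 8 weeks (1.86 and 1.61).

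Clock genes were lower in rods at 2 and 4 weeks (medians -0.62 and -0.61, 11 of 14 members lower; 0.20 at 4 weeks over the 5 members above 100 CPM), Per3 by -1.32 and -0.94, and Cry2 was lower at 8 weeks (-1.49, -1.69 to -1.30). Samd11, a photoreceptor nuclear protein, was lower at 2 and 4 weeks (-2.15 and -2.59) and stood at -0.11 at 8 weeks, and Kansl1l followed it (-1.54, -2.62 and 0.00). Tnip1, an inhibitor of NF-kB signalling, was lower at 4 and 8 weeks (-1.55 and -2.09). Vegfa, which encodes the main factor for growth and leakiness of vessels, stood at 224 CPM in control and 36.3, 107 and 153 CPM in diabetic rods (-2.62, -1.06 and -0.55). The list of immediate early genes had a rod median of -0.88 at 4 weeks and -0.63 at 8 weeks, with Jun at 704, 77.7, 164 and 418 CPM.

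The rods of the 4 libraries fell into unlike clusters: 1 cluster held 76.8% of rods at 2 weeks and 5.3% in control, another 54.6% of control rods, and one more 42.4% of rods at 4 weeks. Within the cluster of most control rods (3050 control cells and 475 cells at 2 weeks), Asns stood at 279 and 24.1 CPM (-3.47, -4.60 to -2.65), Sesn2 at 237 and 16.8 CPM and Ndufa4 at 1052 and 3375 CPM. Within single clusters the oxidative phosphorylation medians were smaller, at 0.10 to 0.54 at 2 weeks, with 0.10 in the cluster of most 2-week rods, and 0.18 to 0.40 at 4 weeks, while glycolysis stood at 0.40 to 0.64 and 0.47 to 0.65. The unfolded protein response stood at -0.58 to -0.19 at 2 weeks, beside medians of all genes of -0.25 to 0.03, at -0.72 to -0.13 at 4 weeks, and at -0.31 to 0.11 at 8 weeks, when it was above 0 in 1 cluster. Asns was lower at 2 weeks within each of the 5 rod clusters with at least 30 cells, by -3.47 to -5.13. The plot of rod genes shows these ratios.

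**Figure D2:**
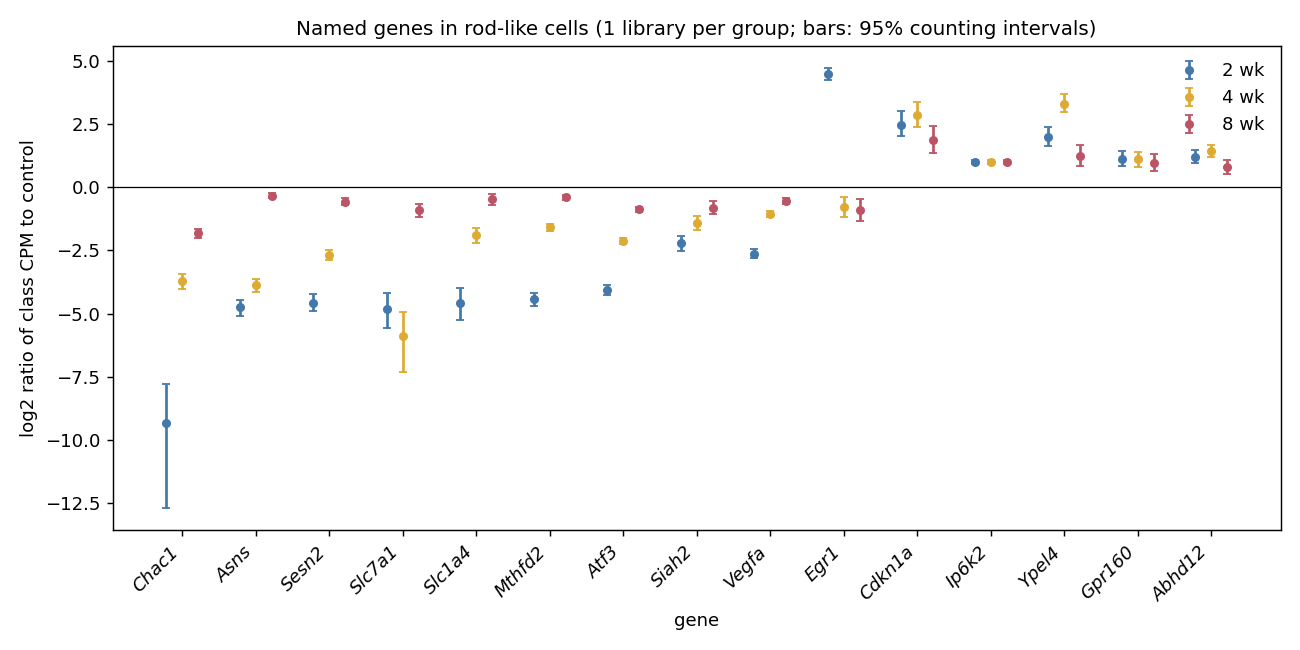
Log2 ratios to control of named genes in rods at 2, 4 and 8 weeks; points are ratios of summed UMIs and bars exact 95% intervals that cover counting error only. Asns lies at -4.75, -3.87 and -0.33, while Ip6k2 lies at 0.99, 1.00 and 1.01.

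In Müller glia, hypoxia genes and Vegfa were higher at 2 and 4 weeks and genes of cholesterol synthesis lower, most at 2 weeks. Vegfa stood at 286 CPM in control and 462, 874 and 319 CPM at 2, 4 and 8 weeks (log2 ratios 0.69, 0.49 to 0.89; 1.61, 1.44 to 1.79; and 0.16, -0.12 to 0.43), opposite in sign to rods at the first 2 times. The hypoxia list had medians of 0.31 and 0.46 at 2 and 4 weeks, with 10 of 14 and 13 of 15 members higher, among them P4ha2, a collagen prolyl hydroxylase, at 1.65 and Ddit4, an inhibitor of mTOR, at 0.78 at 4 weeks. With free RNA subtracted, the 2-week median was 0.21 and no longer apart. Mitochondrially encoded genes, which also vary with the state of the cells, had medians of 0.83, 0.57 and 0.50 in Müller glia, with 13, 12 and 13 of 13 members higher. Hk2, a hexokinase, stood at 69.2, 271, 152 and 88.4 CPM, and the glycolysis list had a median of 0.34 at 4 weeks (14 of 17 higher). Cholesterol synthesis had medians of -0.50, -0.24 and -0.22, with 13, 11 and 11 of 14 members lower (no longer apart under 2 alternatives at 4 weeks and under 4 at 8 weeks, the smallest -0.11), among them Cyp51 (-0.50, -0.68 and -0.61) and Msmo1 (-0.57, -0.37 and -0.45), which both act on lanosterol-derived sterols.

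Txnip, a thioredoxin inhibitor induced by glucose, was lower in Müller glia at all 3 times, at 146 CPM in control and 27.8, 54.7 and 53.5 CPM (-2.37, -3.02 to -1.82; -1.41, -1.89 to -0.97; and -1.43, -2.10 to -0.86). Ednrb, an endothelin receptor, stood at 148, 59.6, 83.1 and 88.4 CPM, and Cxcl14, a chemokine, at 171, 112, 77.8 and 103 CPM. Cadm3 (-1.63, -1.28 and -1.34), Ltbp1, which holds TGF-beta in the matrix (-0.65, -1.16 and -0.86), the small GTPase Arf6 (-0.93, -0.95 and -0.77), Wdr91 and Ccdc43 were also lower at all 3 times. Higher at all 3 times were Bfsp2, a beaded filament protein known from the lens (1.35, 1.78 and 1.41), Etnppl, which degrades phosphoethanolamine (1.13, 1.85 and 1.06), Pdlim4 (1.01, 1.49 and 1.12), C1qtnf5 (0.85, 1.03 and 1.00), Dgkz, a diacylglycerol kinase, and Inpp5b. Histocompatibility genes of the RT1 region differed between libraries without a shared direction: RT1-T24-4 stood at 5.2, 42.7, 61.0 and 92.5 CPM, RT1-S3 at 67.0, 153, 179 and 257 CPM, RT1-A1 at 38.3, 175, 61.0 and 313 CPM, and RT1-A2 at 215, 132, 510.1 and 261 CPM. The ratio of RT1-A1 to RT1-A2 set the 2- and 8-week libraries apart from the others in 6 of 7 classes.

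Gfap, the marker of reactive glia, stood at 21.3, 29.8, 79.9 and 47.3 CPM (0.48, -0.30 to 1.27; 1.89, 1.27 to 2.58; and 1.15, 0.29 to 1.99) but came from few cells, with UMIs in 4, 9, 6 and 9 Müller cells and 69.0% of control and 51.3% of 4-week UMIs in 1 cell. Glul, the glutamine synthetase of these cells, stood at 8587, 6319, 7162 and 8786 CPM. The Müller homeostasis list had a median of -0.27 at 4 weeks (9 of 12 lower), with the water channel Aqp4 at -0.61. Immediate early genes were higher at 2 and 4 weeks (medians 0.54 and 0.67) and lower at 8 weeks (-0.41, and -0.74 without the cell with the most UMIs), with Junb at 126, 522, 202 and 98.7 CPM, but the 2-week median was -0.13 with free RNA subtracted. Targets of apoptosis and p53 had medians of 0.39 and 0.67 at 2 and 4 weeks, 10 of 11 members higher each time, with Gadd45b at 1.82 and 1.46. Heat shock genes were higher at 8 weeks (0.43, 12 of 12 members), with Hspa8 at 0.51. At 4 weeks Slc16a3, a lactate exporter, stood at 81.0 CPM against 19.9 CPM in control (2.01), and Lmcd1 at 86.3 against 15.5 CPM. Prss56, a serine protease of Müller glia tied to eye size, stood at 180 CPM in control, 38.8 CPM at 2 weeks, 1 UMI at 4 weeks (-6.83, -12.72 to -4.92) and 393 CPM at 8 weeks. Ttr, Rpe65, Rgr and Ptgds, high at 2 weeks, had 96.9 to 99.7% of their UMIs in 1 cell. The rod phototransduction list stood at 2.15 and 0.52 in Müller glia at 2 and 4 weeks, a measure of free rod RNA.

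In microglia, chemokine and cytokine genes were lower at 4 and 8 weeks, most at 4 weeks, and the lipid carrier Apoe was higher at all 3 times. Apoe stood at 2862 CPM in control and 4476, 13520 and 11937 CPM at 2, 4 and 8 weeks (log2 ratios 0.65, 2.24 and 2.06). Tnf stood at 227, 87.9, 45.5 and 97.1 CPM (-1.36, -1.78 to -0.98; -2.27, -3.21 to -1.55; and -1.22, -1.63 to -0.84), and Ccl2, which draws monocytes, at 228, 93.0, 55.2 and 77.4 CPM. The list of inflammatory cytokines and NF-kB targets had medians of -0.41, -1.89 and -0.59, with 11 of 17, 13 of 16 and 13 of 16 members lower, although its mean at 2 weeks was 0.25. Il1b stood at 1430, 1074, 302 and 833 CPM, Ccl3 at 4787, 2316, 653 and 2721 CPM, and Ccl4 at 5893, 3634, 77.9 and 3893 CPM (-6.21, -6.88 to -5.67, at 4 weeks). The 2-week median was no longer apart with cells thinned to 1000 UMIs (-0.05) or with free RNA subtracted (-0.04), and the estimated share of free RNA in microglia was 0.325 at 2 weeks against 0.0746 in control.

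Immediate early genes were lower in microglia at 4 weeks in 18 of 18 members, 17 of them at least 2-fold, with a median of -2.26 and with Fos at 4018 and 675 CPM and Jun at 8032 and 1328 CPM. Cholesterol synthesis was lower at 4 and 8 weeks (-1.49 and -0.60), with Idi1 at 493 and 29.2 CPM at 4 weeks, and heat shock genes were lower at 4 weeks (-0.82) and higher at 8 weeks (0.30). The microglial activation list was lower at 2 weeks (-0.66) and higher at 4 weeks (0.61), with the lysosomal genes Cd68 (-1.52 and 1.27), Ctsb (-0.90 and 0.80) and Ctsd (-0.73 and 0.54). With free RNA subtracted the 2-week activation median was -0.55, and within clusters it was -0.05 and -0.42. The homeostasis list stood at -0.55 and -0.45 at 2 and 4 weeks (-0.15 at 2 weeks and -0.61 at 4 weeks within the clusters that allowed it, and -0.15, no longer apart, at 2 weeks with free RNA subtracted), with the purine receptor P2ry12 at -0.58 and -1.24. Fkbp5, a glucocorticoid target, stood at 29.6, 115, 64.9 and 125 CPM, and Capg, an actin-capping protein, at 22.5, 53.5, 182 and 59.1 CPM. Gpx1, a glutathione peroxidase (0.47, 0.54 and 0.57), Mycl, Dtx2 and Dctd were higher at all 3 times, and Cxcl1 and Bcar3 lower. The cholesterol exporters Abcg1 and Abca1 were higher at 4 weeks (2.09 and 1.93), and Cfd, complement factor D, and the small heat shock protein Hspb1 at 8 weeks (3.82 and 1.83). Axl, a receptor for dying cells, was lower at 2 weeks (-2.83), and Cd74, the invariant chain of class II presentation, stood at 561, 290, 201 and 153 CPM.

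Microglia fell into 3 clusters whose shares differed between libraries. The cluster led by Cxcl2, Ccl4, Ccl3 and Il1b held 80 control cells and 102, 6 and 52 diabetic cells. The cluster led by Pld4, Tmem119 and C1qc held 62, 1, 34 and 40, and the remaining cluster 78, 143, 36 and 76. Genes leading the remaining cluster included Aif1, Lyz2, Cd74 and Tyrobp, and Lyz2 was fixed as a macrophage or monocyte marker. That cluster had a median of 1075 UMIs per cell, against 6634 and 5872 in the chemokine and Tmem119 clusters. Its cells may therefore not all be resident microglia. Within the Tmem119 cluster, Apoe stood at 3645 CPM in control and 15364 and 11613 CPM at 4 and 8 weeks (2.08 and 1.67), and the immediate early list had a median of -0.84 at 4 weeks with 7 of 7 members lower. In the remaining cluster that median was -2.92 at 4 weeks and -3.64 at 8 weeks, with 11 of 11 lower each time, so it was not higher at 8 weeks there. The cytokine and NF-kB list stood at -0.39 and -0.11 in the Tmem119 cluster at 4 and 8 weeks, with 3 of 5 members lower, at -3.80 in the remaining cluster at 4 weeks (4 of 5 lower) and at -0.63 in the chemokine cluster at 8 weeks. Ccl4 had 2 control UMIs and none at 4 weeks in the Tmem119 cluster and was higher at 4 weeks in the remaining cluster (1.27), while 6 cells of the chemokine cluster were kept at 4 weeks. Within the chemokine cluster, Tnf was lower at 2 and 8 weeks (-1.80 and -1.36). Several named genes came from few cells: S100a9 (220 UMIs) and S100a8 from 1 control cell, Ccl5 (at least 286-fold higher at 2 weeks) and Gzmk (at least 49.6-fold) from 6 and 5 cells, Egr4 and G0s2 from 9 and 7 control cells, and Cxcr4, Ifitm1, S100a11, Crip1 and Napsa from at most 14 control cells each. The rod phototransduction list stood at 2.69, 0.67 and 0.29 in microglia, so free rod RNA was highest at 2 weeks there. The plot of microglial genes shows the ratios.

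**Figure D3:**
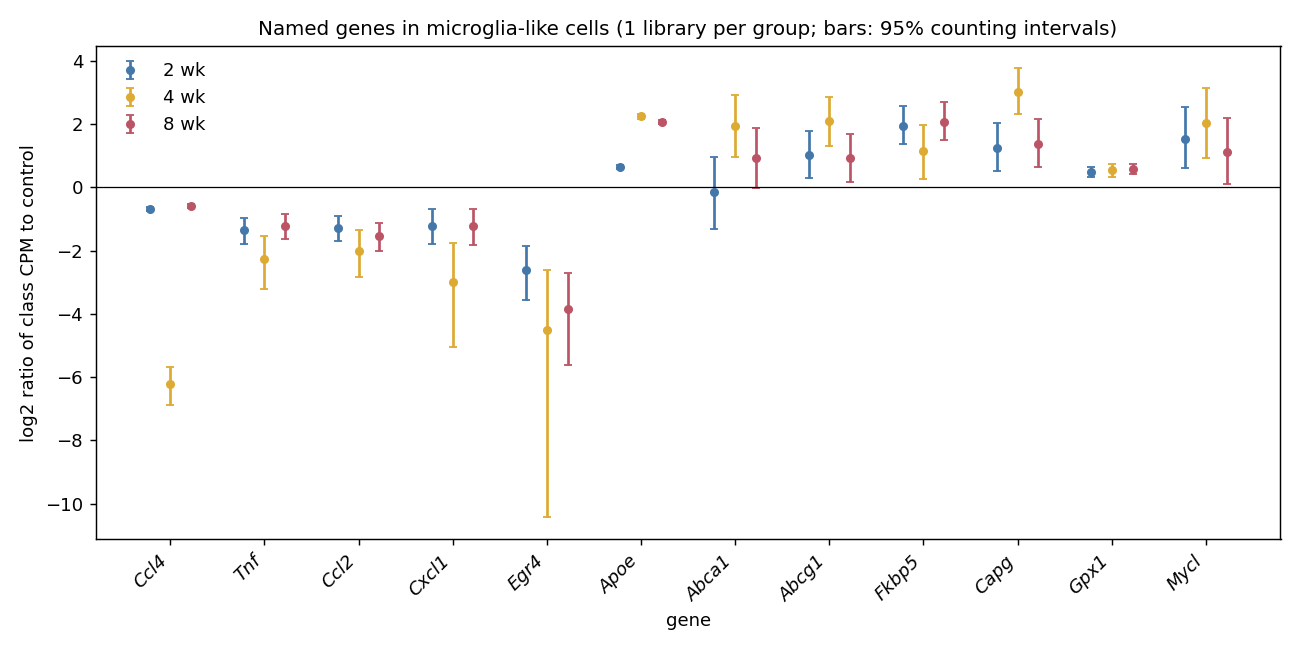
Log2 ratios to control of named genes in microglia at 2, 4 and 8 weeks; points are ratios of summed UMIs and bars exact 95% intervals that cover counting error only. Apoe lies at 0.65, 2.24 and 2.06 and Tnf at -1.36, -2.27 and -1.22.

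In bipolar cells, the interneurons between photoreceptors and ganglion cells, glycolysis genes were lower at 8 weeks, when the estimated share of free RNA was 0.602 against 0.0793 in control, and hypoxia genes were higher at 4 weeks. The glycolysis list had a median of -0.49 at 8 weeks, with 16 of 19 members lower, among them Pgk1 (-0.70) and Aldoa (-0.54). The oxidative stress defence list stood at -0.30 (14 of 15 lower), and the unfolded protein response list at 0.41 (13 of 14 higher), with Herpud1 at 0.81 and Ddit3 at 0.64. The oxidative stress median was 0.03 without the bipolar cluster led by Car8, Pcp2 and Qpct, and the unfolded protein response median -0.37 with free RNA subtracted. The hypoxia list had a median of 0.36 at 4 weeks (13 of 15 higher), with Bnip3, a mitophagy receptor, at 0.58, and was not apart under 4 alternatives (0.14 to 0.20). Cholesterol synthesis stood at -0.38 at 2 weeks and -0.23 at 8 weeks, with 10 of 13 members lower each time.

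Slc1a7, a glutamate transporter of retinal neurons, stood at 59.5, 115, 126 and 137 CPM in bipolar cells, and Nfasc, a cell adhesion protein of axons, at 31.4, 63.0, 58.5 and 79.7 CPM. With at most 10% mitochondrial UMIs the 4-week ratio of Slc1a7 was -0.05. Without the bipolar cluster led by Car8, Pcp2 and Qpct the 8-week ratio of Nfasc was -0.02. Decr2, a peroxisomal enzyme of fatty acid breakdown (1.06, 1.60 and 1.20), the heat shock factor Hsf2, the transcription factor Bhlhe23, the corepressor Tle2, Smim3 and Psmg3 were also higher at all 3 times. Lower at all 3 times were Cxcl14, at 66.2, 4.8, 23.4 and 20.6 CPM, the neurotrophin receptor Ntrk3 (-1.32, -1.14 and -1.60), the transferrin receptor Tfrc (-1.01, -1.45 and -1.31), Fam163b, Pogz, Lrrc73 and Samsn1. The neuropeptide gene Nts stood at 152, 8.3, 1.2 and 37.4 CPM, from 3, 4, 1 and 4 cells, and its 2-week ratio of -4.17 was 0.48 with at most 10% mitochondrial UMIs. At 2 weeks the neuronal splicing factor Srrm4 was higher (1.97, 1.57 to 2.43), with Akap8l and Pycard, and Zcchc12 (-1.65) and Zg16b (-2.79) were lower. Ppp1r3c, which targets a phosphatase to glycogen, was higher at 4 weeks (2.51). Sparcl1, a matrix protein, stood at 368, 410, 108 and 46.3 CPM, and Dbh and Tceal5 were lower at 8 weeks. With at most 10% mitochondrial UMIs the 8-week ratios of Sparcl1 and Tceal5 were 0.50 and 1.57.

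Bipolar cells came from unlike mixtures: the cluster led by Car8, Pcp2 and Qpct held 8 control cells and 94, 19 and 69 diabetic cells. Its leading genes included Car8, Qpct and Vstm2b, which were fixed as markers of rod bipolar cells. Without it, 15 bipolar genes in place of 34 were at least 2-fold higher at all 3 times, and 4 in place of 12 lower. Class values therefore also vary with the mix of bipolar types. The rod phototransduction list stood at 1.59, 0.99 and 3.04 in these cells. At 8 weeks 1 cell held 125502 UMIs, which is 7.0% of the class. Without it the median of the fatty acid oxidation list was 0.61 in place of 1.37, and that of glucocorticoid targets 0.88 in place of 0.97. The former was -0.50 with free RNA subtracted and the latter -0.20 without the cluster led by Car8, Pcp2 and Qpct. That cell also held 34.5% of the UMIs of Elovl1, which was among the highest genes at 8 weeks.

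In amacrine cells, the inhibitory interneurons of the inner retina, interferon genes were higher at 2 weeks and immediate early genes were higher at 4 and 8 weeks. The class came from unlike mixtures, with 19.8, 10.4, 44.5 and 41.7% of its cells in 1 cluster and 22.6, 39.5, 15.2 and 11.1% in another, and its rod phototransduction list stood at 1.73, 0.48 and 0.84. The interferon and antigen presentation list had medians of 0.84 and 0.40 at 2 and 4 weeks (5 and 6 of 6 members higher), with B2m, the light chain of class I molecules, at 28.7, 171, 50.0 and 30.9 CPM. The 2-week median was 0.45 without the cell with the most UMIs and 0.42, no longer apart, without cells carrying markers of another type. Its 6 members included RT1-A1 (9.8 CPM in control and 42.1 CPM at 2 weeks) and RT1-A2 (22.9 and 35.4 CPM), whose counts alleles may shift. Immediate early genes had medians of -0.29 (-0.11 and no longer apart with at most 10% mitochondrial UMIs), 0.59 and 0.37, with Fos at 269, 79.9, 601 and 308 CPM and Fosb at 53.6, 8.6, 107 and 46.9 CPM. Hypoxia genes stood at 0.25 at 4 weeks (13 of 16 higher). Nuclear-encoded oxidative phosphorylation genes stood at -0.15 at 4 weeks (27 of 31 lower), and cholesterol synthesis at -0.14 and -0.19 at 2 and 8 weeks (0.05 at 2 weeks with thinned cells).

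Igfbp5, which binds insulin-like growth factors, stood at 48.3, 142, 82.5 and 110 CPM in amacrine cells (1.55, 0.77 and 1.18), with ratios of -0.84 and -0.20 at 4 and 8 weeks when cells were thinned to 1000 UMIs, and the growth factor gene Igf1 itself at 156, 289, 73.2 and 68.5 CPM. Fbxo2, a ubiquitin ligase component for glycoproteins (0.91, 1.05 and 0.84), Smim17, Epdr1 and Il3ra were also higher at all 3 times. Sec14l3 (-5.54, -2.65 and -0.86), Pkib, an inhibitor of protein kinase A (-0.83, -5.32 and -5.13), Glra3, a glycine receptor subunit (-1.70, -1.92 and -0.61), Prr35 and Psd3 were lower at all 3 times. At 2 weeks Chrna3, a nicotinic receptor subunit, stood at 10.1 against 84.9 CPM in control, and Grm2, a glutamate receptor, at 15.8 against 64.0 CPM. The cluster led by Glra3, Grm2 and Chrna3 held 23, 5, 15 and 18 cells. Crh, corticotropin-releasing hormone, was higher at 4 weeks (2.91), where Aldh1a1 (-2.64) and Dpysl2 (-1.77) were lower. Galnt16 (-1.95) and the autophagy gene Atg7 (-1.37) were lower at 8 weeks. Sncg, known from ganglion cells, had UMIs in 0, 4, 2 and 6 cells, and was at least 181-, 86.0- and 332-fold higher. At least 2 UMIs of ganglion cell markers were carried by 0, 3, 1 and 5 cells of the class. Prph (1 control UMI), Nefm and Nrn1 were also higher. At 4 weeks, however, none of these 3 was higher without the cell with the most UMIs (-0.16, -0.38 and -0.16). Adcyap1 at 2 weeks came from 1 cell.

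In cones, the photoreceptors of bright light, phototransduction genes were lower at 2 and 4 weeks. The cone phototransduction list had medians of -0.19 and -0.50, with 8 of 12 and 9 of 11 members lower, in 94, 180, 53 and 115 cells. The estimated share of free RNA in cones was 0.133 in control and 0.231 and 0.077 at 2 and 4 weeks. The rod phototransduction list stood at 0.47 and -0.27 in cones at these times. The small 2-week cone median could therefore not be told apart from dilution by free RNA. Pde6c, the cone phosphodiesterase, stood at 528, 317, 199 and 538 CPM and Arr3, the cone arrestin, at 3766, 2689, 1884 and 3620 CPM. The green-sensitive opsin Opn1mw stood at 1079, 775, 499 and 1065 CPM, while the short-wavelength opsin Opn1sw stood at 1464, 1876, 2017 and 2870 CPM. Both opsins, Pde6c, Arr3 and several other list members were among the markers that named the cone class. Their values therefore describe cells picked partly by these genes. Cholesterol synthesis was lower at 2 and 8 weeks (-0.54 and -0.49, with 5 of 5 and 6 of 6 members lower), and glycolysis at 8 weeks (-0.30). Clock genes were higher at 8 weeks (0.42, 8 of 8 members).

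Abhd12 (1.32, 1.98 and 1.32), Ip6k2 (0.59, 0.99 and 0.93) and Asmt (0.50, 0.78 and 0.66) were higher in cones at all 3 times, as in rods. So were Crot, which moves medium-chain acyl groups out of peroxisomes (1.36, 0.81 and 0.78), Slc25a28, a mitochondrial iron carrier, Sat2, Abhd14b and Nfyb. Igf2bp2, an RNA-binding protein, stood at 147, 86.7, 23.1 and 18.4 CPM, and the monocarboxylate transporter Slc16a8 (-1.84, -0.96 and -1.03), Hopx (-1.10, -0.86 and -0.77), the small heat shock protein Hspb6, Shisa8, Plod1, Dhx29 and Bud31 were lower at all 3 times. At 2 weeks Srrm4 (3.09) and Egr1 (3.49) were higher and Opa1, which fuses mitochondrial inner membranes, was lower, at 18.4 against 59.3 CPM. At 4 weeks Ypel4 (2.98), Cd63 (2.51) and Acy1 (2.51) were higher and the transcription factor Pax4 lower (-2.41, -3.33 to -1.68). Ccdc136 was higher at 8 weeks (1.74).

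The third comparison set the diabetic times against each other. Rod oxidative phosphorylation was lower at 8 weeks than at 2 and 4 weeks (medians -0.69 and -0.42), and rod glycolysis likewise (-0.47 and -0.43). The rod unfolded protein response was higher at 4 than at 2 weeks (0.46). In Müller glia, hypoxia and glycolysis genes were lower at 8 than at 4 weeks (-0.38 and -0.37), as were immediate early genes (-1.02). In microglia, cytokine and NF-kB target genes were lower at 4 than at 2 weeks (-1.55) and higher at 8 than at 4 weeks (1.13), and so were immediate early genes (-2.20 and 1.91), while the chemokine cluster held 6 cells at 4 weeks and 52 at 8 weeks. Microglial activation was higher at 4 than at 2 weeks (1.22) and lower at 8 than at 4 weeks (-0.49). Cone phototransduction was lower at 4 than at 2 weeks (-0.50) and higher at 8 than at 4 weeks (0.52). Bipolar glycolysis was lower at 8 than at 4 weeks (-0.68). The plot of list medians shows 9 lists in the 6 classes.

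**Figure D4:**
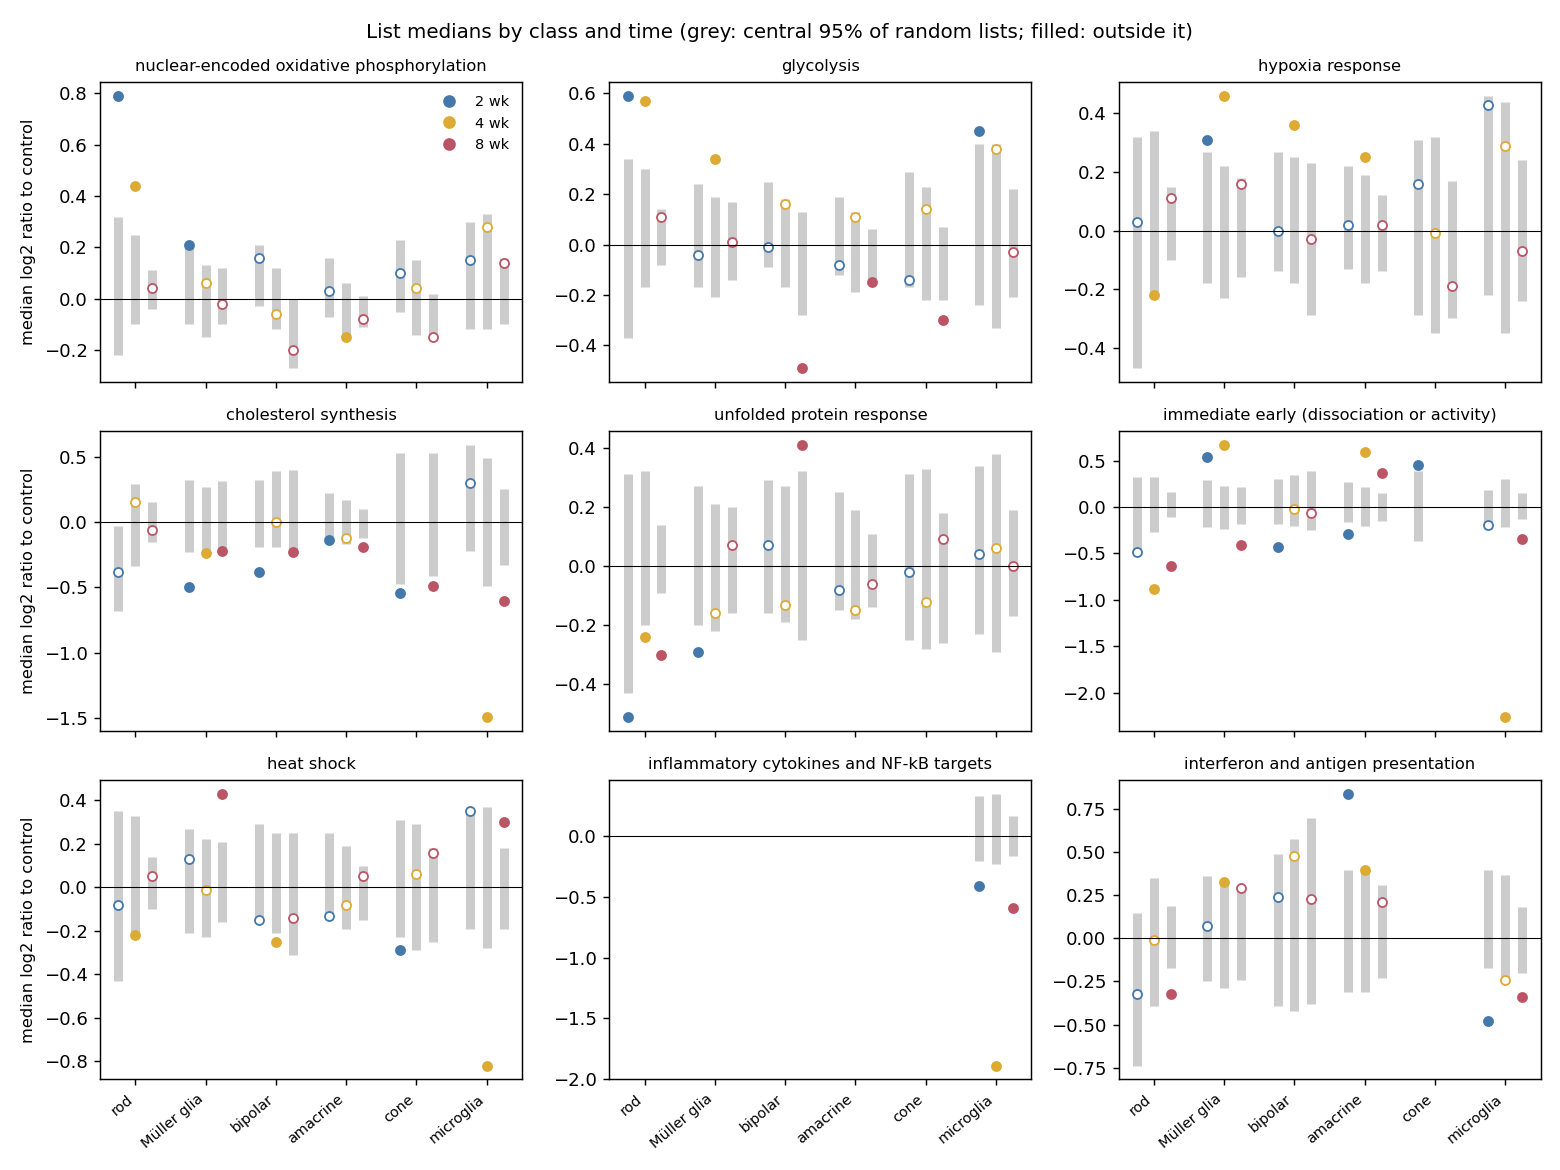
Median log2 ratio to control of 9 gene lists in 6 classes at 2, 4 and 8 weeks; grey bars span the central 95% of 10000 random lists of matched expression and filled points lie outside them. Rod oxidative phosphorylation lies at 0.79 and 0.44 at 2 and 4 weeks, and microglial immediate early genes at -2.26 at 4 weeks.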

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

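All tests in this part were chosen after the results were seen, as was the limit of 0.4 for a list median that marked differences between groups, and none of these differences was itself tested.

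At 2 weeks, named lower rod genes, led by Chac1, Asns and Sesn2, had a median log2 ratio of -4.24 over 12 genes. With cells below 1000 UMIs left out and the rest thinned to 1000 UMIs, the median was -4.21. Thinning keeps the expected ratio of summed UMIs, so it cannot test depth, and this speaks only against cells below 1000 UMIs. With at most 10% mitochondrial UMIs the median was -4.10, which argues against rods rich in mitochondrial RNA as the cause. Over 19 pairs of 8 of these genes with another class, the ratio elsewhere lay a median of 2.98 above that in rods, but the genes were picked as lowest in rods, and over 70 pairs of the fixed unfolded protein response list the difference was 0.19 (-0.36 to 1.19). A first test of handling, on 11 members of the unfolded protein response list, gave -0.05 in amacrine cells and -0.11 in rods, which met its rule for handling, but it was read as undecided after the result was seen, because these members were hardly lower in rods. Handling, of every class or of rods alone, and diabetes, diet, age or animal, stay open, since 1 library per group was analysed.

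RT1 genes, of the rat histocompatibility complex, differed between libraries in Müller glia, microglia and endothelial cells. The ratio of RT1-A1 to RT1-A2 placed the 2- and 8-week libraries highest in 6 of 7 classes (in Müller glia the log2 ratios were -2.48, 0.40, -3.05 and 0.26). Rods were the exception, with -0.66, -1.01, -1.39 and -0.98, although they held the most UMIs of both genes. The 6 classes go with animals that carried different RT1 alleles, which count differently against 1 reference. Alleles would show in every class, and rods lack that order, so this explanation stays open. For higher antigen presentation in diabetes, 8 of 9 RT1-A1 ratios lay above 0 and 1 lay below. RT1-A2 in microglia stood at 1842 CPM in control and at 461 and 694 CPM at 2 and 8 weeks. The interferon and antigen presentation list was lower at 2 and 8 weeks in microglia (-0.48 and -0.34, or -0.27 with free RNA subtracted and -0.19 with doublets kept). It was also lower at these times in endothelial cells (-0.53 and -0.33) and higher in Müller glia at 4 weeks (0.33). The list holds RT1-A1, RT1-A2 and other RT1 genes, whose counts alleles may shift. It therefore cannot decide, and higher antigen presentation stays open.

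In microglia the immediate early list stood at -2.26 at 4 weeks. It stood at -2.35 without cells carrying markers of T or NK cells, B cells or neutrophils, which argues against those cells in control. Cells with macrophage or monocyte markers were not left out, so these were not tested. With cells below 1000 UMIs left out and the rest thinned, the list stood at -2.29 over 15 genes. Thinning keeps the expected ratio of summed UMIs, so this speaks only against cells below 1000 UMIs. In 2 of 4 other classes the list was higher at that time, which argues against handling that acted on all classes alike. Within the 2 clusters that could be compared it stood at -2.92 and -0.84, with every used member lower, which argues against a shift of cells among clusters as the whole cause, although the chemokine cluster held 80 control cells and 6 at 4 weeks. Depth of the cells, macrophages or monocytes in control, handling that acted on microglia alone, diabetes, age and diet stay open.

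The immediate early list differed in direction between classes at 4 weeks, by 1.55 between Müller glia and rods, 1.47 between amacrine cells and rods, 2.93 between Müller glia and microglia, and 2.85 between amacrine cells and microglia. At 2 weeks it differed by 0.97 between Müller glia and bipolar cells and by 0.88 between cones and bipolar cells. Within Müller glia it was higher at 2 and 4 weeks and lower at 8 weeks, by differences of 0.95 and 1.08, but with free RNA subtracted its 2-week median in Müller glia was -0.13, opposite in sign, which bears on the 0.95 and the 0.97. The complement list in Müller glia stood at -0.40 at 2 weeks and 0.64 at 8 weeks, a difference of 1.04. The glial reactivity list in microglia stood at 1.03 at 2 weeks and at -0.83 and -0.59 later, differences of 1.86 and 1.62. It rested on 5 used members, and the estimated share of free RNA in microglia was 0.325 at 2 weeks against 0.0746 in control. The microglial activation list in microglia differed by 1.27 between 4 and 2 weeks, and by 1.07 between amacrine cells and microglia at 2 weeks. The interferon list differed by 1.32 between amacrine cells and microglia at 2 weeks, where the amacrine median of 0.84 was 0.45 without the cell with the most UMIs and 0.42, no longer apart, without cells carrying other markers. In cell types outside the comparisons, shares at 2 weeks were above control by log2 ratios of 1.36 for endothelial cells, 2.20 for pericytes and smooth muscle, and 1.91 for unnamed cells.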

How the results depend on the processing

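The tests that kept up to 40% mitochondrial UMIs, left out cells with markers of another type, left out the cell with the most UMIs or left out a diabetic library were chosen after the results were seen. No paired analysis was possible because only 1 library per group was analysed. Of 138 list medians apart from random lists, 136 stayed apart in the same direction under TMM scaling, 127 without the cell with the most UMIs, 99 with at most 10% mitochondrial UMIs and 67 with cells thinned to 1000 UMIs. With free RNA subtracted, 59 of 114 did and 16 changed sign. The rest include medians that could not be computed because too few genes were left. These were 12 with at most 10% mitochondrial UMIs, 27 with thinned cells and 15 with free RNA subtracted. Apart from changes that follow from a threshold or from fewer genes, cells or libraries, the cause was not tested.

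Rod shares at 2 weeks had log2 ratios of -0.31 with at least 1000 UMIs, -0.08 over every barcode and -0.10 with up to 40% mitochondrial UMIs. Müller ratios were -0.29 (10%), -0.38 (every barcode) and -0.42 (40%) at 2 weeks, -0.24 (1000 UMIs) and -0.23 (every barcode) at 4 weeks, and -0.96 (1000 UMIs) at 8 weeks. Bipolar ratios were -0.13 (10%), 0.08 (every barcode) and 0.14 (40%) at 2 weeks, -0.30 for both every barcode and 40% at 4 weeks, and 0.84 (1000 UMIs), 0.84 (every barcode) and 0.93 (40%) at 8 weeks. The amacrine ratio at 4 weeks was -0.25 with each library clustered alone.

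In the order rods, Müller glia, bipolar cells, amacrine cells, cones and microglia, 8, 14, 46, 13, 7 and 16 genes were at least 2-fold from control at all 3 times. Thinning gave 13, 7, 14, 8, 1 and 6, a mean CPM of 100 gave 3, 3, 14, 3, 2 and 2, 1.5-fold gave 55, 98, 216, 85, 54 and 84, and 3-fold gave 3, 3, 6, 2, 0 and 7. Without the 2-week library there were 13, 28, 99, 25, 15 and 68, without the 4-week library 15, 32, 92, 32, 12 and 33, and without the 8-week library 179, 38, 71, 33, 28 and 61. A mean CPM of 5 gave 34 in rods, 26 in amacrine cells and 26 in microglia. In bipolar cells there were 25 with at most 10% mitochondrial UMIs, 10 with up to 40% and 17 with doublets kept. Bipolar cells gave 25 with free RNA subtracted and 19 without the cluster led by Car8, Pcp2 and Qpct. In amacrine cells there were 5 with doublets kept, 7 with free RNA subtracted, 8 without cells of other markers, 8 without the cell with the most UMIs and 38 with each library clustered alone. In cones there were 4 with at most 10% mitochondrial UMIs and 4 without the cell with the most UMIs.

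These medians were no longer apart. The rod unfolded protein response was -0.39 at 2 weeks (CPM of 5) and -0.19 (10%) and -0.17 (CPM of 5) at 4 weeks. Müller hypoxia at 2 weeks was 0.21 (free RNA) and 0.28 (40%). Müller cholesterol synthesis was -0.35 (thinned) and -0.29 (free RNA) at 4 weeks, and -0.11 (clustered alone), -0.32 (thinned), -0.21 (free RNA) and -0.20 (cell with the most UMIs left out) at 8 weeks. Bipolar hypoxia at 4 weeks was 0.20 (10%), 0.16 (doublets kept), 0.18 (40%) and 0.14 (CPM of 100), and bipolar cholesterol synthesis at 2 weeks -0.21 (thinned). Amacrine interferon genes at 2 weeks were 0.42 (other markers) and immediate early genes -0.11 (10%). Microglial cytokine and NF-kB targets at 2 weeks were -0.05 (thinned) and -0.04 (free RNA). Nts in bipolar cells at 2 weeks was 0.48 (10%).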

Other observations

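No test is reported in this part. Endothelial cells, with 39 cells at 4 weeks, fell below the limit for comparison, and their values were chosen after they were seen. The calcium-binding protein gene S100a6 stood at 129 CPM in control and 715, 465 and 426 CPM at 2, 4 and 8 weeks, and Acer2, an alkaline ceramidase, at 227, 733, 1111 and 599 CPM. RT1-T24-4 stood at 42.7, 417, 524 and 415 CPM while RT1-T24-3 stood at 895, 312, 356 and 307 CPM. The interferon regulator Irf7 stood at 72.4, 14.7, 28.4 and 30.9 CPM and the transferrin receptor Tfrc at 147, 49.4, 36.6 and 68.5 CPM. The immediate early list stood at -0.47, 0.36 and -0.57 at 2, 4 and 8 weeks. The rod phototransduction list, a measure of free rod RNA, stood at 2.03, 0.92 and 0.38 in these cells. Cholesterol synthesis genes had medians of -0.72 and -0.68 at 4 and 8 weeks, with 13 of 14 members lower each time. Rgs5, a pericyte gene, stood at 516, 156, 230 and 258 CPM in these cells.

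The unnamed gene AABR07039356.2 had 1141 UMIs in the control library and 0 in each diabetic library. The gene AC134224.3 took 10.45, 6.86, 10.29 and 9.08% of all UMIs.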
